A study of Sus scrofa with 8 samples.

How the data were processed

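Expression was measured in biceps femoris muscle of female domestic piglets with an Affymetrix porcine array, 1 array per sample, in a model of the muscle weakness that follows intensive care. The 4 control and 4 corticosteroid arrays were assigned from the sample titles. Per the labels' protocols, all piglets were sedated with isoflurane and mechanically ventilated for 5 days, and the treated piglets received bolus doses of hydrocortisone. The protocols differ in other ways as well. The text for the control samples speaks of 4 piglets with a mean weight of 25.5 kg and adds an endotoxin infusion, which the source label of the same samples leaves out. The text for the corticosteroid samples speaks of 8 piglets with a mean weight of 26.4 kg and of no endotoxin. The design text of the series also describes an infusion of a neuromuscular blocker without saying which animals received it. No text covers samples of both groups, so a processing batch or an endotoxin effect cannot be told apart from the group. The labels do not state that each array came from its own animal, so p-values measure the spread between these samples.

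The deposited values are log2 expression levels per probe set, with 23999 probe sets and nearly the same distribution on all arrays. The submitters' processing notes name MAS5 only, and how the authors scaled the arrays to each other is not given in the sources used here. The array medians ran from 5.873 to 5.972, so no further scaling was applied. The number of arrays limits the precision, and the log2 difference had a median standard error of 0.219 over the probe sets tested.

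The columns of the 2 groups did not appear to be in the same row order in the deposited table. The probe IDs are in plain character order, and the control values were taken to follow it. The corticosteroid values matched the control values far better in the order obtained when the full stops in the IDs are ignored, which leaves 14610 probe sets at the same row and puts 9389 (39.1%) at another. The corticosteroid values were therefore re-assigned to the IDs in that order, which uses the text of the IDs only and has 0 tied IDs. The order itself was found from the values, by comparing the correlation of group means under a few ways of ordering the IDs. The check that used no comparison between groups took pairs of probe sets of the same gene more than 50 rows apart. The planned test, samples and threshold were kept, the re-ordered rows give the reported values, and the rows as deposited are given as an alternative.

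Probe sets were named from the platform's annotation table. A single gene symbol was given for 10069 probe sets, several for 198 and none for 13732. Of those with 1 symbol, 9961 were found in the current porcine gene table by gene ID, and 0 symbols had to be updated. Probe sets with several symbols were not named. The 64 reporter probe sets were left out. The table used here held 0 probe sets of the array's control kind, so the planned test of the difference between 3′ and 5′ control probe sets was not run. No genome build is named in the sources used here, and no coordinates are given.

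Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment at 0.05. The test covered the 14361 probe sets whose mean log2 level over the 8 arrays lay above the 40th percentile. A gene was represented by its probe set of highest mean level, which gave 5406 genes. Before the data were examined, 37 gene lists were fixed, 9 of them markers of cell types. The 34 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. Members were also adjusted over the list alone. The mean level of each list on each array, centred per gene, was compared with an exact two-sided permutation test, whose smallest possible p with 4 arrays against 4 is 0.0286. This last test was added after the data were seen. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

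The genes to be named were also set beforehand. They were the largest changes among genes past the threshold or, with fewer than 10 such genes, the 10 of smallest p in each direction. Up to 4 members of smallest p were added for each list described, and NR3C1, FKBP5, TSC22D3, FBXO32 and TRIM63 whatever their result. Alternatives covered a block for the replicate number, quantile normalization, centring on the array median, no filter or a filter at the 60th percentile, 16 added to the linear value before log2, other variance models, array weights, averaging the probe sets of a gene and leaving out each array. Added after the data were seen were the rows as deposited, the unmoved rows only, and a fit without control array 2 and corticosteroid array 4.

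The fit was tested on simulated data with the spread of the 14361 tested probe sets, in 10 draws with 50 changed probe sets of each size. It recovered 4.4% of changes of 0.5 log2 units, 44.0% of 1, 85.6% of 2 and 96.4% of 3, and 5.2% of its calls were false. All sizes were present in the same draw, and the noise was independent between probe sets. The larger changes ease the adjusted threshold for the smaller ones, so these shares do not hold where large changes are absent. With a list shifted by -0.4 log2 units in simulated values of 5406 genes without correlation between genes, camera called that list in 10 of 10 draws and 0 of 320 lists that were not shifted.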

Results

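Gene expression was profiled in biceps femoris, a hind-limb muscle, of female piglets kept sedated and mechanically ventilated for 5 days. This porcine model is used to study acute quadriplegic myopathy, the limb muscle weakness of intensive care patients. The 4 control arrays came from piglets given sedation and ventilation, and the 4 corticosteroid arrays from piglets that also received hydrocortisone, a glucocorticoid. The protocol text of the control samples also names an endotoxin infusion, which their source label does not. The comparison asked how corticosteroid treatment alters the muscle transcriptome under these conditions. The median log2 signal was 5.891 ± 0.015 (SD, n = 4) on corticosteroid arrays and 5.918 ± 0.037 (SD, n = 4) on control arrays, a difference within the spread between arrays (exact two-sided permutation p = 0.229). The deposited values had nearly the same distribution on all arrays, so this comparison decides nothing about signal or RNA quality before processing.

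Some abundant muscle transcripts, in rows that the re-ordering described here moves, stood far apart between the groups in the table as deposited. Creatine kinase (CKM) had a mean log2 level of 13.93 in control muscle and 7.67 in corticosteroid-treated muscle in the table as deposited, and 14.03 once the corticosteroid values were re-ordered by the text of the probe IDs. The giant filament protein titin (TTN) stood at 13.62 in controls, at 7.47 as deposited and at 13.53 after re-ordering. The fast myosin light chain MYLPF stood at 13.93, 5.49 and 14.06. Over the 14610 probe sets whose row was the same in both orders, the group means correlated across probe sets with r = 0.9887. Over the 9389 others the correlation was 0.0997 as deposited and 0.9888 after re-ordering. Probe sets, which are not independent replicates, are the units of these correlations. Pairs of probe sets of the same gene gave a check within each group. Over 1529 such pairs more than 50 rows apart, the levels correlated with r = 0.298 in controls as listed and 0.057 when re-ordered. In the corticosteroid group r was 0.042 as listed and 0.306 when re-ordered. The values below use the re-ordered corticosteroid columns. They rest on an order found from the data, and 39.7% of the tested probe sets lay in rows that it moved.

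**Figure D1:**
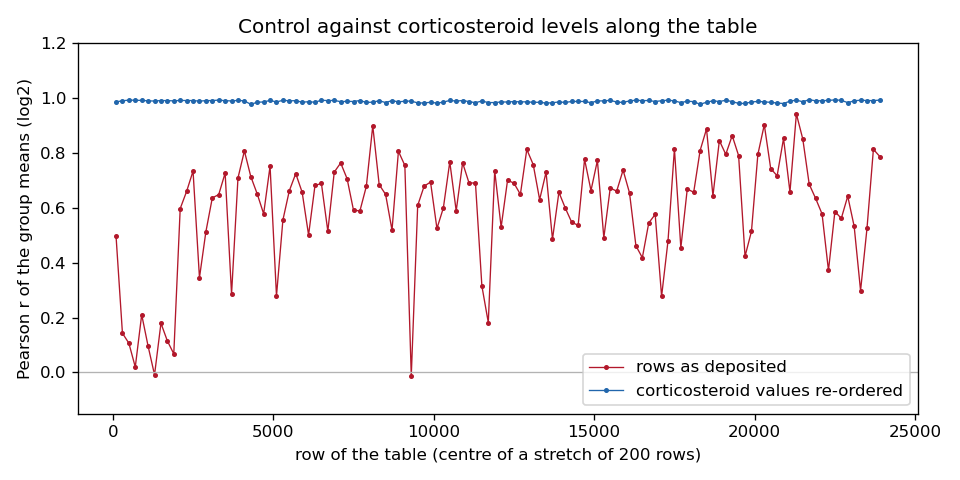
Pearson correlation of the control and corticosteroid group means (log2) in successive stretches of 200 rows along the deposited table, with each point a stretch. As deposited (red) the lowest stretch had r = -0.0123, and with the corticosteroid values re-ordered (blue) the lowest had r = 0.9766.

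Corticosteroid-treated muscle had lower mean levels over the heat shock and slow-fibre lists and higher ones over the fast-fibre, glycolysis and ribosomal protein lists, but these calls rest on a preset correlation between genes. None of them held with an estimated correlation (adjusted p of 0.703 or more). Of the members of these 5 lists, 4 slow-fibre genes passed when adjusted over the list alone, and 0 members of the other 4 lists did. The mean log2 difference was -0.54 over 47 heat shock proteins and chaperones and -0.79 over 12 slow-fibre genes. It was 0.57 over 12 fast-fibre genes, 0.31 over 24 glycolysis and glycogen genes and 0.10 over 56 ribosomal proteins. Camera, with a preset correlation between genes, called 10 of the 34 lists tested. With an estimated correlation it called 0 of 34, and fry called 0 of 34. In the exact permutation test of the array scores 0 of 34 lists passed after adjustment, with a smallest adjusted p of 0.555. Even a few lists at its smallest possible p of 0.0286 could not have passed after adjustment over 34 lists. This 0 of 34 therefore decides nothing about single lists. Amino acid genes had the smallest exact p before adjustment (0.0286). It was 0.0571 for heat shock and slow-fibre genes, 0.0857 for glycolysis, 0.114 for ribosomal proteins and 0.143 for fast-fibre genes. The other called lists had 0.2 for antioxidant genes and macrophage markers, 0.343 for the unfolded protein response, 0.4 for cytokines and 0.571 for the proteasome. No single gene passed the limma test. Of 14361 probe sets, 0 had an adjusted p under 0.05 and the smallest adjusted p was 0.469. At an unadjusted p under 0.05 there were 1363 probe sets (9.49%), 687 higher and 676 lower with corticosteroid. When each array was left out, this number ran from 892 without corticosteroid replicate 4 to 1783 without control replicate 1. It was 902 without control replicate 3. The groups did not overlap for 5.56% of probe sets, against an expected 2.86% by chance. Probe sets are correlated across the arrays, and how far this share varies between regroupings was not tested. In simulated data of the same spread the fit found 44.0% of changes of 1 log2 unit and 85.6% of changes of 2. Those draws held changes of all sizes together, and larger changes ease the adjusted threshold for smaller ones. The shares therefore do not give the chance of finding a change of 1 log2 unit in the real data. With the rows as deposited, the same fit called 5454 probe sets, of which 5119 lay in rows that the re-ordering moved.

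Among the 12 slow-fibre genes, 10 had lower means with corticosteroid, and 4 passed when adjusted over the list alone, all lower. These were slow troponin T (TNNT1), the calcium pump of slow and cardiac muscle (ATP2A2), slow myosin heavy chain (MYH7) and the slow myosin regulatory light chain (MYL2). TNNT1 had a mean log2 level of 9.41 ± 0.43 (SD, n = 4) with corticosteroid and 11.19 ± 0.85 (SD, n = 4) in controls, a difference of -1.78 (SE 0.40). The difference was -1.07 (SE 0.26) for ATP2A2, -1.17 (SE 0.32) for MYH7 and -0.98 (SE 0.28) for MYL2. All 4 treated arrays lay below all 4 control arrays for each of these genes. Over all probe sets tested none passed, with adjusted p-values in limma of 0.469 for TNNT1, ATP2A2 and MYH7 and 0.479 for MYL2. The list had a camera adjusted p of 1.7e-05, and an adjusted p of 0.703 with an estimated correlation. The array scores of the list overlapped, because control replicate 4 (-0.318) lay among the treated arrays (exact two-sided permutation p = 0.0571, adjusted p = 0.555). Without control replicate 2 or without control replicate 3 the list-alone count was 3, and without control array 2 and corticosteroid array 4 it was 0. It was 8 without control replicate 4 and 6 without corticosteroid replicate 3.

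All 12 fast-fibre genes had higher means with corticosteroid, and 0 passed when adjusted over the list alone. Fast troponin T (TNNT3) differed by 0.66 (SE 0.21) and fast troponin C (TNNC2) by 0.43 (SE 0.17), with all treated arrays above all controls. TNNC2 differed by 0.25 without control replicate 2. The difference was 0.59 (SE 0.21) for tropomyosin 1 (TPM1) and 1.17 (SE 0.46) for muscle phosphofructokinase (PFKM). The list's camera adjusted p was 0.00012, with an adjusted p of 0.808 with an estimated correlation. Control replicate 2 had the lowest score of the 8 arrays (-0.942), and without it the mean difference of the list was 0.35 (adjusted p = 0.00234, and 0.905 with an estimated correlation). The 24 glycolysis and glycogen genes included 17 with higher means, 0 of them past the threshold over the list alone. Muscle phosphoglycerate mutase (PGAM2) differed by 0.79 (SE 0.22), the lactate transporter SLC16A3 by 1.54 (SE 0.49), glycerol phosphate dehydrogenase (GPD1) by 1.10 (SE 0.37) and triose phosphate isomerase (TPI1) by 0.89 (SE 0.35). Without corticosteroid replicate 4 SLC16A3 differed by 1.02, and its control mean log2 level of 5.33 lay close to the filter level of 5.27. That list had a camera adjusted p of 0.00499 and an adjusted p of 0.808 with an estimated correlation. Without control replicate 3 its mean difference was 0.20 (adjusted p = 0.0246, and 0.802 with an estimated correlation).

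**Figure D2:**
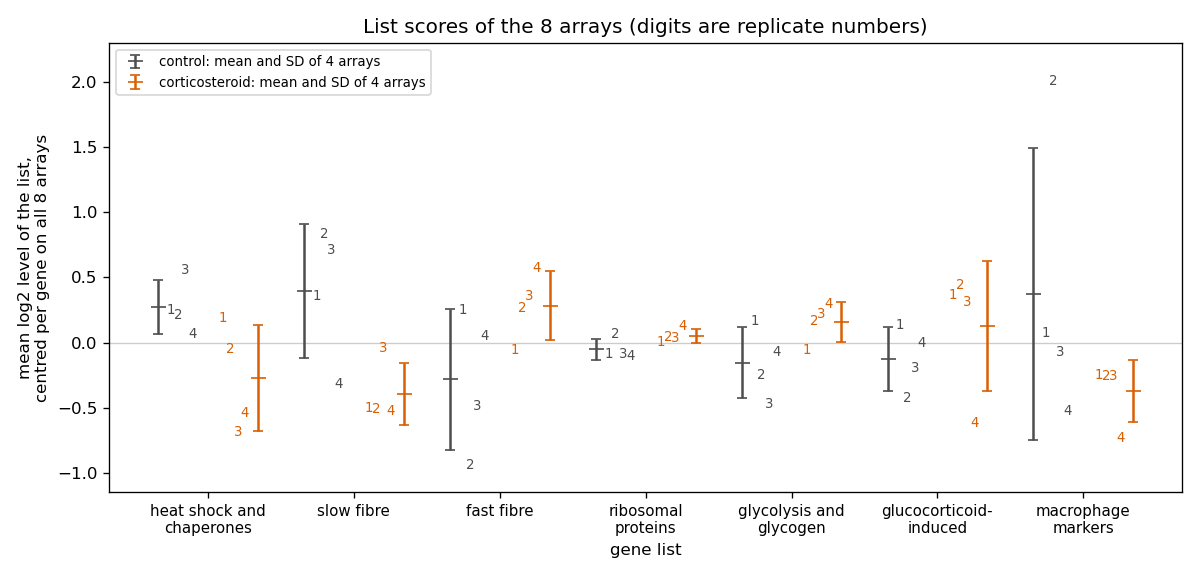
Score of 7 gene lists on each of the 8 arrays, as the mean log2 level of the list's tested genes centred per gene on all arrays. Digits mark the replicate number of control (grey) and corticosteroid (orange) arrays, and bars give the mean and SD of 4 arrays. Control replicate 2 stands at 2.012 for macrophage markers, and corticosteroid replicate 4 at -0.618 for glucocorticoid-induced genes.

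Heat shock proteins and chaperones had the smallest camera p of the lists at the preset correlation. With an estimated correlation the slow-fibre, amino acid and denervation lists had a smaller unadjusted p than they did. In fry the amino acid, slow-fibre and ribosomal lists did. Of 47 members, 40 had lower means with corticosteroid, 17 of them at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone. The mitochondrial chaperonin HSPD1 had a mean log2 level of 11.10 ± 0.43 (SD, n = 4) with corticosteroid and 12.01 ± 0.29 (SD, n = 4) in controls. The difference was -1.67 (SE 0.54) for the co-chaperone DNAJA4, -1.01 (SE 0.34) for the cytosolic chaperone HSPA4 and -1.05 (SE 0.36) for HSP90B1, a chaperone of the endoplasmic reticulum. The camera adjusted p was 5.33e-10, and the adjusted p was 0.703 with an estimated correlation. The score was -0.272 ± 0.409 (SD, n = 4) on treated arrays and 0.272 ± 0.206 (SD, n = 4) on control arrays (exact two-sided permutation p = 0.0571, adjusted p = 0.555). The lowest scores were those of corticosteroid replicates 3 (-0.685) and 4 (-0.539). The groups overlapped, because corticosteroid replicate 1 (0.188) lay above control replicate 4 (0.069). Corticosteroid replicate 2 stood at -0.051.

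Other lists of protein quality control were called in the same direction with larger p-values. The unfolded protein response list shares HSP90B1, its member of smallest p (-1.05, SE 0.36), with the heat shock list. The calls of these lists are therefore not separate. For the unfolded protein response, 16 of 22 members had lower means (camera adjusted p = 0.0467, adjusted p = 0.808 with an estimated correlation), among them HYOU1 at -0.89 (SE 0.34), HSPA5 at -0.90 (SE 0.42) and PDIA4 at -0.69 (SE 0.34). All are chaperones or folding enzymes of the endoplasmic reticulum. They differed by -0.59, -0.44 and -0.35 without control replicate 2. The call was lost without control replicate 2, whose score was 0.707 (mean difference -0.09, adjusted p = 0.504). It was also lost without control replicate 3 (adjusted p = 0.0955), corticosteroid replicate 2 (0.054) or corticosteroid replicate 4 (0.254), and in quantile-normalized values (0.0546). For proteasome subunits, 22 of 33 means were lower, with PSMB6 at -0.43 (SE 0.20), PSMD1 at -0.77 (SE 0.38), PSMB7 at -0.61 (SE 0.32) and PSMD2 at -0.37 (SE 0.20). The camera adjusted p was 0.037, and the adjusted p was 0.808 with an estimated correlation. Leaving out corticosteroid replicate 4 brought the mean difference of the proteasome list from -0.15 to 0.01 (adjusted p = 0.678). The call also ended without control replicate 1 (adjusted p = 0.0987), control replicate 3 (0.18), control replicate 4 (0.159) or corticosteroid replicate 2 (0.222). The mean difference was -0.35 without corticosteroid replicate 1 and -0.25 without control replicate 2. Without corticosteroid replicate 4, PSMD1 differed by -0.42, PSMB7 by -0.36 and PSMD2 by -0.24. Without corticosteroid replicate 1, PSMB7 differed by -0.93 and PSMD2 by -0.56, and without corticosteroid replicate 3 PSMB6 differed by -0.28. No member of either list passed over the list alone.

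For antioxidant and metallothionein genes, 21 of 34 means were lower (camera adjusted p = 0.0284, adjusted p = 0.808 with an estimated correlation) and 0 members passed over the list alone. Ferritin heavy chain (FTH1), an iron store, differed by -0.20 (SE 0.08), with all treated arrays below all controls. The difference was -1.07 (SE 0.39) for the quinone reductase NQO1, -1.07 (SE 0.40) for mitochondrial superoxide dismutase (SOD2) and -0.68 (SE 0.27) for thioredoxin (TXN). The call ended without control replicate 2 (mean difference -0.14, adjusted p = 0.22) and without corticosteroid replicate 2 (adjusted p = 0.054), and the mean difference was -0.14 without corticosteroid replicate 4.

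Ribosomal protein genes had higher means for 41 of 56 members, by small amounts, and 0 passed over the list alone. The difference was 0.27 (SE 0.09) for RPS10 and 0.35 (SE 0.13) for RPL34, each with all treated arrays above all controls, and 0.33 (SE 0.11) for FAU and 0.29 (SE 0.11) for RPS9. RPL34 differed by 0.23 without control replicate 4. The camera adjusted p was 0.000365, and the adjusted p was 0.808 with an estimated correlation. After quantile normalization the mean difference was 0.06 and the adjusted p 0.0877. Without control array 2 and corticosteroid array 4, a choice made after the data were seen, fry called the ribosomal list (adjusted p = 0.00695), and camera with an estimated correlation did not (0.11). Nuclear-encoded respiratory chain genes did not pass (camera adjusted p = 0.0977), with 44 of 59 means higher. The complex I subunits NDUFV3 and NDUFB7 differed by 0.70 (SE 0.21) and 0.74 (SE 0.24), and NDUFV1 by 0.64 (SE 0.23). Cytochrome c (CYCS) went the other way, at -0.62 (SE 0.16), with all treated arrays below all controls. The respiratory list was called without control replicate 1 (adjusted p = 0.0238), corticosteroid replicate 2 (0.0211) or corticosteroid replicate 3 (0.016), and its mean difference of 0.11 was 0.0637 without control replicate 3 and 0.0067 without corticosteroid replicate 4. These 3 calls were lost with an estimated correlation, with adjusted p-values of 0.756, 0.841 and 0.751. The 19 genes of amino acid metabolism and transport had 14 higher means (camera adjusted p = 0.0839). The branched-chain keto acid dehydrogenase subunits BCKDHB and BCKDHA differed by 1.19 (SE 0.40) and 0.48 (SE 0.24), alanine aminotransferase (GPT) by 0.79 (SE 0.31) and isovaleryl-CoA dehydrogenase (IVD) by 0.55 (SE 0.28). BCKDHA differed by 0.27 without control replicate 2.

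Genes that glucocorticoids are known to induce did not pass as a list (camera adjusted p = 0.215), with a mean difference of 0.25, 17 of 24 means higher and 0 members past the threshold over the list alone. The clock gene PER1 differed by 0.81 (SE 0.23), the transcription factor CEBPB by 0.62 (SE 0.27), the stress-responsive SESN1 by 0.94 (SE 0.45) and the lipid phosphatase LPIN1 by 0.87 (SE 0.43). FKBP5, a chaperone partner of the glucocorticoid receptor, differed by 0.45 (SE 0.47) and TSC22D3, the leucine zipper protein GILZ, by 0.81 (SE 0.68). Without control replicate 2 these were 0.0893 for FKBP5, 0.22 for TSC22D3 and 0.43 for LPIN1, and without corticosteroid replicate 4 they were 0.85 for FKBP5 and 1.30 for TSC22D3. FKBP5 differed by 0.71 without control replicate 1. The glucocorticoid receptor itself (NR3C1) differed by -0.18 (SE 0.23, adjusted p = 0.794 in limma), by -0.10 without control replicate 4, by -0.0884 without corticosteroid replicate 1 and by -0.37 without corticosteroid replicate 3. The list's scores were 0.364, 0.442 and 0.312 on corticosteroid replicates 1, 2 and 3 and -0.618 on corticosteroid replicate 4, the lowest of the 8 arrays. Without corticosteroid replicate 4 the mean difference of the list was 0.50 and its camera adjusted p 0.000603, with an adjusted p of 0.734 with an estimated correlation. The mean difference was 0.14 without control replicate 2 (adjusted p = 0.603) and 0.14 without corticosteroid replicate 2 (0.632). Ubiquitin ligases and other atrophy genes did not pass either (camera adjusted p = 0.427, 15 of 20 means higher). The muscle ubiquitin ligase FBXO32 differed by 0.24 (SE 0.64), between -0.16 without control replicate 3 and 0.86 without corticosteroid replicate 4. TRIM63 had no probe set with its name alone. The proteases CAPN1 and CAPN3 differed by 0.81 (SE 0.32) and 0.88 (SE 0.43), the growth inhibitor myostatin (MSTN) by 1.17 (SE 0.59) and the ubiquitin-conjugating enzyme UBE2N by -0.48 (SE 0.20). CAPN3 differed by 0.54 without control replicate 2.

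Macrophage and monocyte markers had lower means with corticosteroid for 13 of 14 genes, with a mean difference of -0.75 (camera adjusted p = 0.00106, adjusted p = 0.808 with an estimated correlation) and 0 genes past the threshold over the list alone. LAPTM5, a lysosomal protein of blood-derived cells, differed by -1.55 (SE 0.60), cathepsin S (CTSS) by -1.40 (SE 0.69), the myeloid transcription factor SPI1 by -1.23 (SE 0.65) and the complement component C1QC by -0.57 (SE 0.32). SPI1 was dim, with a treated mean log2 level of 4.915, below the filter level of 5.27, and it stood at 8.480 on control replicate 2. Control replicate 2 had a score of 2.012, while the other control arrays lay between -0.525 and 0.076 and the treated arrays between -0.731 and -0.247. Without it the mean difference was -0.20 and the adjusted p 0.0573, and LAPTM5 differed by -0.87, CTSS by -0.60, SPI1 by -0.45 and C1QC by -0.36. Cytokines and inflammatory mediators had 20 of 27 lower means (camera adjusted p = 0.0429, adjusted p = 0.808 with an estimated correlation), and control replicate 2 again had the highest score (0.937). Without that array the mean difference of the cytokine list was -0.03 (adjusted p = 0.603). The call also ended without corticosteroid replicate 1 (adjusted p = 0.123), 2 (0.0808) or 3 (0.0775), and in quantile-normalized values (0.057). The chemokine CCL2 differed by -1.87 (SE 1.05), the growth factor TGFB1 by -0.88 (SE 0.44), the adaptor MYD88 by -0.52 (SE 0.27) and the chemokine CXCL12 by 0.73 (SE 0.33). CCL2 differed by -0.60, TGFB1 by -0.39 and MYD88 by -0.25 without control replicate 2, and without corticosteroid replicate 4 CXCL12 differed by 0.48. Antigen presentation genes had 15 of 24 lower means and a mean difference of -0.24 (camera adjusted p = 0.0839), with beta-2 microglobulin (B2M) at -0.28 (SE 0.09), PSMB8 at -0.65 (SE 0.35) and SLA-8 at -0.38 (SE 0.22). Their list was called as lower without control replicate 3 (adjusted p = 0.0128), control replicate 4 (mean difference -0.36, adjusted p = 0.00439) or corticosteroid replicate 3 (0.0456), with no filter (0.0269) and with the 60th percentile filter (0.0483). With an estimated correlation these 5 calls were lost, at adjusted p-values of 0.802, 0.689, 0.751, 0.817 and 0.775. Without control replicate 2 its mean difference was -0.0214, with PSMB8 at -0.29 and SLA-8 at -0.23. Markers of endothelium (camera adjusted p = 0.804), smooth muscle and pericytes (0.967), fibroblasts (0.406), adipocytes (0.712) and Schwann cells and nerve (0.601) did not pass. For endothelium the mean difference was 0.09 and the median -0.03. Without 1 array that mean was 0.0380 (control replicate 1), 0.0409, 0.0564 and 0.16 (corticosteroid replicates 1, 2 and 3). For smooth muscle and pericytes camera gave the direction as lower with a median of -0.03. The fibroblast list had a mean difference of 0.14, and without control replicate 2 it was called as higher (mean difference 0.33, adjusted p = 0.0197, and 0.905 with an estimated correlation). Its mean difference was 0.0697 and 0.0039 without control replicate 1 or 3, and 0.0587, 0.23 and 0.0711 without corticosteroid replicate 2, 3 or 4. The mean of the adipocyte list turned from 0.0512 to -0.0511 without control replicate 1 and to -0.15 without corticosteroid replicate 2, and it was up to 0.17 without the other arrays. That of the Schwann cell list turned from 0.14 to -0.0811 without control replicate 4 and to -0.0250 without corticosteroid replicate 1, and it was up to 0.23 without the others. Lymphocyte, erythrocyte and neutrophil markers had 3, 4 and 0 tested members and were not tested as lists.

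The sarcomere list as a whole did not pass (camera adjusted p = 0.626), with 19 means higher and 17 lower, a mean difference of -0.15 and a median of 0.03. The M-band protein myomesin 1 (MYOM1) differed by 1.21 (SE 0.35), opposite to the slow isoforms. Among 14 genes of excitation-contraction coupling (camera adjusted p = 0.861), ATP2A2 alone passed over the list alone. The fast calcium pump ATP2A1 differed by 1.30 (SE 0.58), the calcium-binding HRC by 0.92 (SE 0.40) and the calcium release channel RYR1 by 0.50 (SE 0.26). ATP2A1 differed by 0.63 and RYR1 by 0.23 without control replicate 2, and without corticosteroid replicate 4 HRC differed by 0.61. The call of ATP2A2 over that list ended without control replicate 1, 2 or 3 and without corticosteroid replicate 1 or 3. Extracellular matrix genes were split, 18 higher and 17 lower (camera adjusted p = 0.971), and control replicate 2 had the highest score (0.668). Camera gave the direction as lower, although the mean difference was 0.01 and the median 0.07. Leaving out each array took that mean from -0.10 to 0.24. Periostin (POSTN) differed by 1.31 (SE 0.34), with all treated arrays above all controls, thrombospondin 2 (THBS2) by 1.11 (SE 0.44), tenascin X (TNXB) by 0.71 (SE 0.29) and the collagen chain COL5A2 by -0.71 (SE 0.33). Without control replicate 2 the list was called as higher, with a mean difference of 0.24 (adjusted p = 0.0269, and 0.905 with an estimated correlation), and COL5A2 differed by -0.35.

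Because no gene passed, the 10 of smallest p in each direction are given as measured, each with an adjusted p of 0.469 in limma and with no overlap between the groups. Those with higher means included FHL3, a LIM-domain protein of skeletal muscle, at 1.36 (SE 0.25), and the adhesion protein T-cadherin (CDH13) at 1.28 (SE 0.28). The centromere protein CENPB differed by 0.88 (SE 0.17), the unnamed locus LOC102163508 by 1.17 (SE 0.24), the DNA polymerase subunit POLD4 by 0.82 (SE 0.18) and the chromatin remodelling subunit INO80C by 0.89 (SE 0.20). The others were AKTIP at 0.86 (SE 0.19), CITED1 at 0.87 (SE 0.21), the adipokine chemerin (RARRES2) at 0.70 (SE 0.17) and the dynein light chain DYNLT1 at 0.74 (SE 0.18). Those with lower means included TNNT1 and ATP2A2, given above, and the membrane scaffold EFR3A, which had the smallest p, at -0.76 (SE 0.14). Sorbitol dehydrogenase (SORD) differed by -1.31 (SE 0.29), the autophagy regulator TP53INP2 by -1.26 (SE 0.29), the phospholipid transfer protein PLTP by -1.16 (SE 0.28) and the tyrosine phosphatase PTPN1, which acts on the insulin receptor, by -0.94 (SE 0.23). LRMDA differed by -0.67 (SE 0.14), the RNA-binding ZC3H13 by -0.67 (SE 0.16) and SRFBP1 by -0.81 (SE 0.20). Without control replicate 3, 1 probe set passed, for the aldo-keto reductase AKR1CL1, with a difference of -1.88 (adjusted p = 0.013, against 0.469 with all arrays). It is named because it was the only one, after its value was seen. In that setting 0 genes passed, so the probe set of highest mean level that represents AKR1CL1 was another one and did not pass. Whether these differences belong to the corticosteroid, to the endotoxin named in the control protocol or to separate processing of the groups cannot be told apart.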

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

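The tests of the row order, of single arrays and of fibre makeup below were chosen after the results were seen. The regroupings of the arrays were set before their results were seen, except those of single gene lists.

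The groups of 4 values tested, each a gene, a list or the array median in 1 group, numbered 252. In 14 of them an array lay far from the other 3, where chance alone gives about 12.6 if they are independent. They are not, since lists and their own members were counted on the same arrays. The values in parentheses are the gap to the nearest other array divided by the range of the group. In the corticosteroid group, replicate 4 was the low array for FKBP5 (0.943), TSC22D3 (0.886), the glucocorticoid-induced list (0.877) and the macrophage list (0.979). Replicate 3 was the high array for NR3C1 (0.838), the slow-fibre list (0.951) and the interferon list (0.911). In the control group, replicate 2 was the high array for PDIA4 (0.954), COL5A2 (0.918), the ribosomal list (0.923) and the denervation list (0.885). Control replicate 1 was high for CENPB (0.925), control replicate 3 low for SLC16A3 (0.884) and control replicate 4 low for RPL34 (0.932).

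The first pattern is the 5454 probe sets past the threshold in the table as deposited. The splits of the arrays cannot test chance here, although 1 of 35, the real one, gave as many and the highest of the others gave 0. Every other split puts columns of both apparent row orders into the same group, which by itself widens the spread within groups. A real difference in expression between the groups as the source is argued against by the probe sets at the same row in both orders, whose group means correlated with r = 0.9887 as deposited. The row order may be the source, because re-ordering by the text of the IDs brought the other probe sets to r = 0.9888. The order was found on the same values, so this stays a hypothesis until the original scans are compared.

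The second pattern is the lower heat shock list. Control replicate 2 as its only source is argued against by its score of 0.210, below the control mean of 0.272. With such a score, leaving it out could not shrink the mean log2 difference, which was -0.55 without that array and -0.54 with it. The difference was -0.39 without corticosteroid replicate 3, -0.43 without control replicate 3 and -0.45 without corticosteroid replicate 4. Without any other array it lay between -0.70 and -0.54. A smaller share of slow fibres in the treated biopsies stays open, since with the slow-fibre score as a covariate the difference was -0.54 but its 95% interval ran from -1.5405 to 0.4567. A processing batch shared with the group cannot be told apart from treatment, because 0 protocol texts cover both groups. The corticosteroid and the endotoxin named for the controls both stay open and untested.

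The third pattern is the lower macrophage list, whose 14 tested genes include 4 that another list also holds. Control replicate 2 alone may be its source, since the mean log2 difference was -0.75 with that array and -0.20 without it. Fewer immune cells of every kind in the treated biopsies cannot be told apart from fewer macrophages. The lymphocyte list differed by 0.022 (SE 0.192) and the macrophage list by -0.75 (SE 0.574), but the lymphocyte list had 3 tested genes, fewer than the minimum of 5.

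The 8 arrays make 35 splits into 4 and 4, the real one included. For probe sets past the threshold the real count was 0 and the highest other 3, and for genes 0 and 1. With a real count of 0, 35 of 35 splits give as many whatever the data hold, so these 2 comparisons decide nothing. For the other results of the re-ordered rows chance could not be excluded. For probe sets at an unadjusted p under 0.05, 2 of 35 splits gave as many as the real 1363, the other being 1784. That split exchanged control replicate 1 and corticosteroid replicate 1, and it also gave the 3 probe sets past the threshold. For called lists, 14 of 35 splits gave at least the real 10, and the highest other gave 15. For the slow-fibre list, 3 of 35 splits gave a camera p as small. It was 1e-06 in the real split and 3.05e-13 in the smallest other, which exchanged control replicate 4 and corticosteroid replicate 3. A camera p as small was given by 4 of 35 splits for the heat shock list (1.57e-11 in the real split, 2.7e-15 in the smallest other), 8 of 35 for the fast-fibre list (1.06e-05 and 8.99e-09) and 12 of 35 for the macrophage list (0.000156 and 2.05e-09).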

How the results depend on the processing

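The rows as deposited, the unmoved rows and the fit without control array 2 and corticosteroid array 4 were chosen after the data were seen. With the re-ordered rows, 0 probe sets and 0 genes passed under every alternative, except that leaving out each array gave 0 to 1 probe sets. Probe sets at an unadjusted p under 0.05 ranged from 828 with the unmoved rows only, where fewer are tested, to 2160 with no filter. The replicate numbers did not pair the arrays: same-numbered arrays correlated with r = -0.246, 0.109, 0.105 and 0.053 in their deviations, and not every array correlated best with its own number. With the replicate number as a block, 0 probe sets passed, 1332 had an unadjusted p under 0.05 and 9 lists were called, so the proteasome call was lost (adjusted p = 0.0597). Lists called ranged from 7 to 12 when each array was left out. The count was 6 with the unmoved rows only (fewer genes are tested), 3 with the rows as deposited, 0 with an estimated correlation and 0 with fry.

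With an estimated correlation and with fry the adjusted p was 0.703 and 0.585 for the heat shock list (-0.54), 0.703 and 0.533 for the slow-fibre list (-0.79), 0.808 and 0.658 for the fast-fibre list (0.57) and 0.808 and 0.727 for the macrophage list (-0.75). Leaving out each array gave a mean difference from -0.70 to -0.39 for heat shock, -1.03 to -0.65 for slow-fibre and 0.35 to 0.75 for fast-fibre genes. All were still called at the preset correlation. With an estimated correlation none was, at adjusted p-values of 0.264 or more. The mean difference was -1.05 to -0.20 for macrophage markers, whose call ended without control replicate 2. The difference between array medians stayed between -0.0353 and -0.008. Without both control array 2 and corticosteroid array 4, calls ended for macrophage markers (-0.0801, adjusted p = 0.367), the unfolded protein response (0.0038, 0.993), antioxidant genes (-0.0370, 0.39) and cytokines (-0.0613, 0.367). Glucocorticoid-induced genes (0.40, 0.00291) and amino acid genes (0.28, 0.0285) were then called, and the fast-fibre (0.25, 0.019) and proteasome (-0.0827, 0.0456) lists still were. With an estimated correlation these 4 adjusted p-values were 0.281, 0.432, 0.79 and 0.948. Ribosomal proteins were called by fry in that setting (0.00695) but not with an estimated correlation (0.11). Calls also ended with probe sets averaged for ribosomal proteins (0.0901), antioxidant genes (0.0799) and the unfolded protein response (0.0799), and with array weights for antioxidant genes (0.0942), cytokines (0.175) and the unfolded protein response (0.253), all adjusted p-values. They ended with quantile normalization for ribosomal proteins (0.0877), cytokines (0.057) and the unfolded protein response (0.0546), with no intensity trend for the last of these (0.0514), and with the 60th percentile filter for cytokines (0.135). With the unmoved rows only they ended for the unfolded protein response (0.647), proteasome (0.282), cytokines (0.183) and antioxidant genes (0.175). The rows as deposited ended those of antioxidant genes (0.127) and the unfolded protein response (0.0889). Leaving out 1 array moved 33 of 91 named genes by over 1.5 times, 24 without control replicate 2 and 9 without corticosteroid replicate 4.

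Some lists that were not called turned direction. Leaving out each array took the mean of the extracellular matrix list from -0.10 to 0.24, of excitation-contraction coupling from -0.0576 to 0.163 and FBXO32 from -0.16 to 0.86. The means of the sarcomere list (-0.20 to -0.10) and of the respiratory chain (0.0067 to 0.153) kept their sign. Only the direction in camera turned for these 2, without control replicate 1 (-0.12) and without corticosteroid replicate 4 (0.0067), and for coupling without control replicate 2 (0.0133). The direction in camera also turned for the matrix list with the block (0.0128), the 60th percentile filter (0.0827), array weights (0.16) and without both arrays (0.20), and fry gave that list as higher (0.0128) where camera gave lower. It turned for excitation-contraction coupling with array weights (-0.0183) and without both arrays (-0.10), for the respiratory chain without both arrays (0.0056) and for the sarcomere list in unmoved rows (-0.0752). The cause was not tested.

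With the rows as deposited, 5454 probe sets and 2001 genes passed. The slow-fibre list had a mean difference of -1.73 (adjusted p = 0.23) and macrophage markers -0.0864 (0.905). These lists turned direction: fast-fibre genes (-1.26), ribosomal proteins (-2.89), glycolysis (-1.01), cytokines (0.99), atrophy genes (-1.13) and the respiratory chain (-1.51). So did 22 named genes, with log2 differences of -7.18 for FHL3, -0.47 for CENPB, -1.35 for POLD4, -1.60 for INO80C, -3.54 for AKTIP, -5.67 for DYNLT1, 0.26 for SORD, 4.23 for PTPN1, -6.36 for FKBP5, -4.75 for TSC22D3, -6.73 for TNNC2, -5.09 for FAU, -5.90 for RPL34, -8.38 for PGAM2, -0.87 for TPI1, -2.04 for CXCL12, 0.51 for CCL2, 0.82 for SPI1, -4.69 for CAPN3, -1.39 for RYR1, -0.63 for GPT and -1.11 for THBS2. Of the other comparisons of named genes with an alternative, 1792 kept direction and side of the threshold and 36 passed the threshold, all with the rows as deposited. How signal over background limits dim probe sets was not analysed here. The planned test of 3′ and 5′ control probe sets was not run.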

Other observations

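Genes of the muscle's response to denervation and of the neuromuscular junction had 7 of 9 lower means with corticosteroid, with a mean log2 difference of -0.52 (camera adjusted p = 0.0951). The stress-responsive ankyrin repeat protein ANKRD1 differed by -1.54 (SE 0.58), the chemokine CCL2, which the cytokine list also holds, by -1.87 (SE 1.05), the acetylcholine receptor subunit CHRNA1 by -0.47 (SE 0.31) and the potassium channel KCNN3 by -0.39 (SE 0.29). The list was called without control replicate 2 (adjusted p = 0.0442) and without corticosteroid replicate 1 (0.0402), with adjusted p-values of 0.789 and 0.716 with an estimated correlation. Without control replicate 2 CCL2 differed by -0.60, CHRNA1 by -0.19 and KCNN3 by -0.59, and KCNN3 differed by -0.23 without control replicate 1 and by -0.19 without control replicate 4. Among 7 clock genes, 6 had higher means (camera adjusted p = 0.445), and PER1 passed when adjusted over the list alone (adjusted p = 0.047). That call ended without control replicate 1, 2 or 3 and without corticosteroid replicate 1, 2 or 4.

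Interferon response genes had 16 of 26 lower means (camera adjusted p = 0.134). Control replicate 1 (0.744) and corticosteroid replicate 3 (0.746) had high scores, and the other 6 arrays lay between -0.405 and -0.002. The list was called as lower without control replicate 4 (mean difference -0.31, adjusted p = 0.00439) and without corticosteroid replicate 3 (mean difference -0.42, adjusted p = 2.62e-05). With an estimated correlation the adjusted p was 0.755 and 0.725. The mean difference of the interferon list turned from -0.15 to 0.0723 without control replicate 1 (adjusted p = 0.811). It was -0.0408, -0.0748 and -0.0626 without corticosteroid replicate 1, 2 or 4. Autophagy and lysosome genes (camera adjusted p = 0.409, 20 of 32 means lower), cell cycle genes (0.116, 11 of 14 lower), complement and acute phase genes (0.617), apoptosis genes (0.409), myogenic regulators (0.622), growth signalling genes (0.62), fatty acid oxidation genes (0.793) and genes of the TCA cycle (0.422) did not pass. For fatty acid oxidation camera gave the direction as higher, while the mean difference was -0.02 and the median 0.07, and the mean turned to 0.0154 without control replicate 1 and 0.0552 without corticosteroid replicate 4, and was down to -0.0663 without corticosteroid replicate 2. The mean of the complement list turned from 0.0555 to -0.0113 without control replicate 4, and was up to 0.13 without control replicate 2. For myogenic regulators the mean was 0.13 and the median -0.01, and the mean was 0.0287 without control replicate 3 and 0.0654 without corticosteroid replicate 4. The cell cycle list had its highest score, 0.989, on control replicate 2, and without that array its mean difference went from -0.24 to 0.05 (adjusted p = 0.853). It was called as lower without control replicate 3 (adjusted p = 0.0246), without control replicate 4 (mean difference -0.38, adjusted p = 0.0102) and with no filter (0.00103), but with an estimated correlation the adjusted p was 0.802, 0.712 and 0.817.

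The first principal component, with 36.3% of the variance, put control replicate 2 at 62.9 and corticosteroid replicate 4 at -42.2, at opposite ends of the 8 arrays. Their median correlations with the other arrays across the 14361 tested probe sets were 0.894 and 0.923, the lowest of the 8.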
